A study of Homo sapiens with 6 samples.

How the data were processed

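Expression was measured on Illumina HumanHT-12 v4 BeadChips in 6 samples, 1 per group: H1 cells (passage 50), H1 cells after 24 h and 48 h of BAP, H1BP cells at passage 7 and passage 18, and H1BP cells of passage 7 after 10 days of differentiation. The groups followed the sample labels, and no column of the deposited table was left unused. The deposited values are probe intensities on a linear scale, from 96.8 to 31560. The series text names background subtraction in BeadStudio, a percentile shift and a filter on detected probes in GeneSpring 12.6, and gives no BeadStudio version. Neither the subtraction nor the filter is visible in the values: all 47323 probes are present, none is below 0, and the lowest value of an array is 108.7 or 96.8. The sorted values of H1, both undifferentiated H1BP samples and differentiated H1BP matched within 0.1% for 99.9% to 100% of probes, and so did those of both BAP arrays, as quantile normalization within each set gives. Between the sets only 0.00845% of sorted values matched so closely, with medians of 149 and 128 and 75th percentiles of 260.3 and 200.2. The background left in the values compresses the fold differences of dim genes.

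Of the probes, 30113 carried 1 gene symbol, 8 carried several and 17202 none; only the first were used. Symbols were checked against a RefSeq table, which held 30074 of these probes' symbols and lacked 39. They stood for 20046 genes, 6691 of them with more than 1 probe, and the probe with the highest mean signal represented its gene. Each array was scaled to a common 75th percentile and put on a log2 scale. The floor was the 50th percentile of all scaled values (145), a value under the floor was set to the floor, and a gene was compared where it lay above the floor in at least 1 of the 2 samples. A gene under the floor in 1 sample of a pair could therefore only be lower in that sample, which can tilt the median of a list of such genes. In all, 16658 genes were above the floor in at least 1 sample: 11627 to 11839 per array in the larger set, but 15214 and 15223 in the BAP arrays. A fold against a sample under the floor is a lower bound and is given as "at least". The floor lay at 57.5% of probes in the larger set but at 35.1% in the BAP arrays, whose value at that higher rank was 160. By a rule chosen after seeing the data, a fold against a BAP value under 160 is therefore also given as "at least". The rule does not correct a BAP value set against an H1 or H1BP value under the floor, so such bounds hold for this scaling only. It also leaves H1 and H1BP values just above the floor without "at least", and folds against these are close to bounds. With 1 array per group the number of arrays limits the precision, and no error, p-value or test was computed; a gene counted as different where its log2 difference was 1 or more in size. There were 10 comparisons between pairs of samples.

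The 29 gene lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. For each comparison, named genes were the 8 with the largest difference in each direction among genes above the floor in both samples, the 4 with the largest bound in each direction, up to 4 members of each list with the largest absolute difference, and 15 fixed genes. The text names those that it describes. Among 800 named differences of 2-fold or more, 281 had another probe above the floor, 142 had another probe that differed by under 2-fold, and 0 had one that differed by 2-fold the other way. A list with at least 5 measured members was described by the median log2 difference of its members and the percentile of that median among 10000 random lists of the same size, drawn from genes matched by decile of mean signal. Lists overlap in members: HAND1, for example, is in the trophectoderm, BMP target and heart and muscle lists. Similarity was Pearson's r and average-linkage clustering of Euclidean distances across genes. Overlaps between comparisons that share the H1 array were set beside 200 simulated sets of unchanged samples sharing 1 control, with noise taken from the difference of the H1BP samples by signal level. That difference also holds any real difference between those samples.

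The steps were tested on simulated data, H1 against a copy of H1 with known differences. All 33 genes made 3-fold higher and 35 made 6-fold higher were recovered, but 19 of 30 made 3-fold lower and 24 of 34 made 6-fold lower, since the floor hides losses of dim genes. Of 11931 unchanged genes, 2.30% passed 2-fold. Among 200 simulated lists without a difference 8 stood apart, and all 200 lists of 20 genes with a log2 shift of 0.5 did.

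Alternatives to the choices above were: quantile normalization, a shift to the median or no shift between arrays; the floor halved or doubled; genes above the floor in both samples, or no filter and no floor; the mean of all probes; normexp background correction with an offset of 50; random lists not matched on signal; and sizes of 1.5-fold and 3-fold. The floor was set anew under each scaling, and within a set, where all arrays have nearly equal scaling, only that acts. The halved floor (72.3) lay below every scaled value (lowest 99.6), so it gave the same values as no filter and no floor. Chosen after seeing the data were a count of BAP genes that also differed from both H1BP samples, and overlaps of comparisons that share no array. Leaving out replicates was not possible with 1 sample per group. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.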

Results

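Gene expression was measured on Illumina HumanHT-12 v4 arrays in 6 samples of the human embryonic stem cell line H1 and of lines derived from it, with 1 array in each of 6 groups. Untreated H1 cells at passage 50 were the reference. A pair of arrays held H1 cells after 24 h and 48 h in BAP, a mixture of BMP4 with inhibitors of activin/TGF-β and FGF receptor signalling that drives stem cells toward trophoblast. The other 3 arrays held H1BP cells, lines grown from colonies picked after 24 h of BAP: undifferentiated cells at passage 7 and passage 18, and passage 7 cells left to differentiate for 10 days in medium without FGF2. H1 cells were grown in mTeSR1, and undifferentiated H1BP cells in fibroblast-conditioned medium with FGF2 at 10 ng/ml, so line and medium differed together. Between 11627 and 15223 of 20046 genes lay above the signal floor of 145. With 1 array per group there was no replicate error and no test, so every difference below is between single arrays. The deposited values fell into 2 separately normalized sets, one of both BAP arrays and one of the other 4, so a difference between a BAP array and an array of the other set also holds any difference between the sets. A gene list was said to stand apart where its median log2 difference lay at or below the 2nd or at or above the 98th percentile of 10000 random lists of similar signal, which describes these arrays and is no test. Over the 285 list medians in 10 comparisons, 145 stood apart. Lists of genes drawn at random would give 11.4. Members of a real list can vary together, lists share genes and comparisons share arrays, so the 11.4 is no measure of chance here. Where a list is said to have lost its call, it no longer stood apart on the same side of random lists under the alternative settings named or counted. Counts of settings take the halved floor and no filter, which gave equal values, as 1. The median given with them is the one nearest 0 among those settings.

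The undifferentiated samples resembled each other closely, and the differentiated H1BP sample lay farthest from all. Across 16658 genes, which are not independent replicates, Pearson's r was 0.972 between H1 and H1BP at passage 7, 0.969 between H1 and H1BP at passage 18, and 0.975 between the H1BP passages. The BAP samples correlated with each other at 0.978, and with H1 at 0.962 after 24 h and 0.939 after 48 h. The differentiated sample correlated with the other 5 at between 0.877 (H1) and 0.925 (48 h of BAP). Clustering joined the BAP pair and the undifferentiated H1BP pair first, then H1 with the H1BP pair, and the differentiated sample last. The number of genes at least 2-fold different ranged from 293 between the BAP times to 2151 between differentiated H1BP and H1. As shares of the genes compared, these were 1.79% and 16.5%. Pairs among H1, 24 h of BAP and the undifferentiated H1BP samples had between 2.57% and 3.69%. In the simulated pair 2.30% of unchanged genes passed 2-fold, so counts near that share need not mark differences between the samples.

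**Figure D1:**
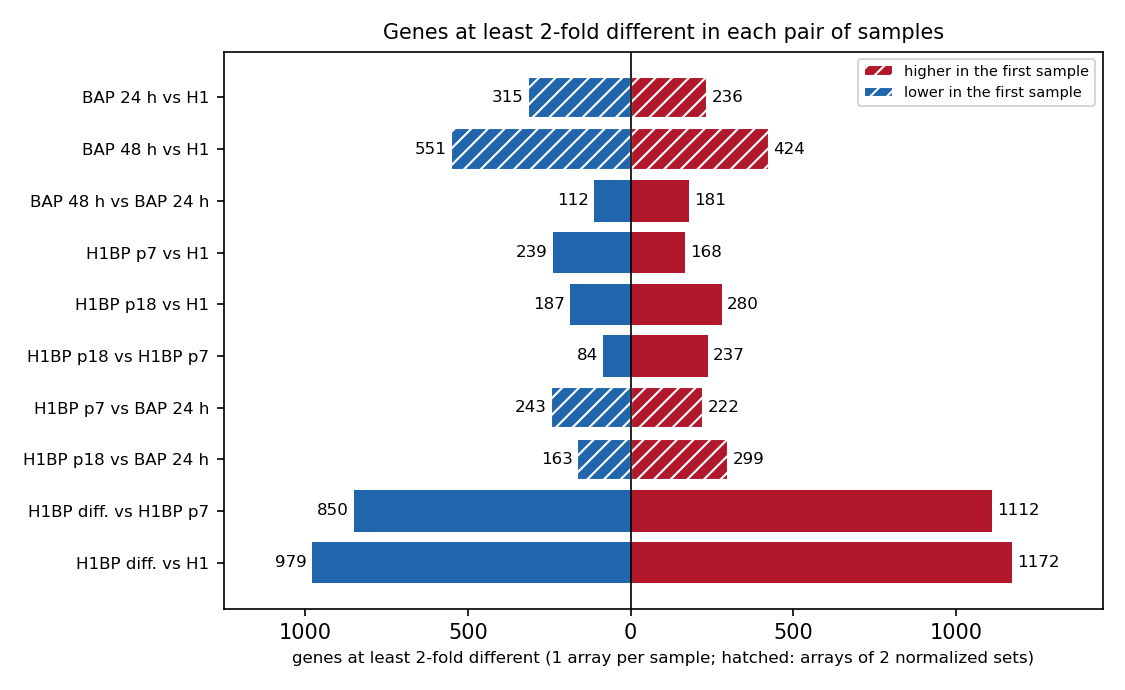
Genes at least 2-fold higher (right) or lower (left) in the first sample of each pair, on a linear axis of gene counts, with 1 array per sample. Hatched bars mark pairs from 2 normalized sets; differentiated H1BP against passage 7 had 1112 higher and 850 lower genes, the BAP times 181 and 112.

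After 24 h of BAP, targets of BMP signalling and early trophoblast regulators were higher than in H1. Of the BMP target list, 11 of 20 measured genes were at least 2-fold higher (median log2 difference 1.27), among them ID1 (29.8-fold), an inhibitor of basic helix-loop-helix factors, and SMAD6 (12.8-fold), an inhibitory SMAD. Of the trophectoderm and early trophoblast list, 10 of 25 were at least 2-fold higher (median 0.75), with the transcription factors HAND1 (at least 40.5-fold), TFAP2A (at least 39.9-fold), DLX5 (at least 20.7-fold) and TFAP2C (14.7-fold). GATA2 and GATA3 were at least 2.64-fold and at least 2.44-fold higher, and CDX2 at least 1.47-fold. Other lists that stood apart on the higher side were amnion (0.46, with ISL1 at least 8.81-fold higher), heart and muscle (0.41), surface ectoderm and keratinocyte (0.17) and epithelial adhesion (0.31, but -0.034 without scaling). The heart and muscle list held NPPB, a natriuretic peptide (30.9-fold), and the muscle actins ACTA1 (22.9-fold) and ACTC1 (17.0-fold). Outside the lists, SPP1 (16.0-fold), which encodes osteopontin, and SERPINB9 (at least 8.82-fold), an inhibitor of granzyme B, were among the highest.

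The gene lists with the lowest medians after 24 h of BAP covered metal handling, FGF signalling, glucose metabolism and the pluripotent state. The metallothioneins, which bind zinc and copper, had a list median of -2.51, with 7 of 9 at least 2-fold lower, including MT1G (18.6-fold), MT1H (14.9-fold) and MT1M (at least 3.36-fold). FGF and ERK targets had a median of -1.05, with 10 of 19 at least 2-fold lower, including the feedback phosphatase DUSP6 (10.2-fold) and SPRY1 (6.52-fold). The glycolysis and hypoxia list had a median of -0.90, with 11 of 29 lower by that size, including BNIP3 (10.8-fold) and the glucose transporter SLC2A1 (5.32-fold). Primed pluripotency genes had a median of -0.31 with 10 of 29 at least 2-fold lower, led by DUSP6, ZIC2 (9.56-fold) and THY1 (4.50-fold); NANOG was 2.56-fold lower, POU5F1 1.66-fold and SOX2 1.33-fold. The interferon and HLA list also stood apart (-0.28), and EDNRB, the endothelin B receptor (16.2-fold), PLA2G4C, a phospholipase (11.1-fold), and STMN2, a neuronal stathmin (10.1-fold), were among the lowest. In all, 236 of 15386 genes were at least 2-fold higher and 315 lower, so that 42.8% were higher, against 26.3% with arrays shifted to their medians and 12.8% without scaling. In a count chosen after seeing the data, 53 of the 315 (16.8%) were also at least 2-fold lower than in both undifferentiated H1BP samples. The metallothionein and glycolysis lists were below H1 in those samples as well. The H1 and BAP arrays came from different sets, and surface ectoderm lost its call against random lists not matched on signal. Another probe differed by under 2-fold for TFAP2A, ACTC1, SERPINB9 and MT1H.

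After 48 h of BAP, the differences from H1 were more numerous, and on the higher side amnion and trophoblast lists had the largest medians. Of the trophectoderm and early trophoblast list, 20 of 27 were at least 2-fold higher than in H1 (median 2.21), with HAND1 (at least 114-fold), TFAP2A (at least 51.0-fold), DLX5 (at least 31.8-fold), the hypoxia-response factor EPAS1 (at least 23.8-fold) and the keratin KRT7 (at least 9.02-fold). CDX2, a trophectoderm transcription factor, was at least 6.00-fold higher and GATA3 at least 5.84-fold. The amnion list had 12 of 17 at least 2-fold higher (median 2.36), including ISL1 (at least 25.8-fold), MEIS2 (at least 12.6-fold), ANXA1 (12.1-fold) and IGFBP3, a binding protein for insulin-like growth factors (22.2-fold). BMP targets had 12 of 20 higher by that size (median 1.87), including ID1 (22.1-fold) and MSX1 (14.5-fold). Epithelial adhesion (0.65), heart and muscle (0.25), surface ectoderm and keratinocyte (0.22) and naive pluripotency (0.17, but -0.048 without scaling) also stood apart on the higher side. Further large differences were in WLS, the carrier of secreted WNT proteins (28.1-fold), AHNAK (26.2-fold), the membrane protein STOM (20.1-fold), the chemokine receptor ACKR3 (17.4-fold) and HAPLN1 (at least 31.8-fold), which links hyaluronan to proteoglycans. The placental hormones and mature trophoblast list did not stand apart (0.06), and CGA, the alpha subunit of chorionic gonadotropin, stood at 148, near the floor.

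On the lower side at 48 h, 14 of 27 primed pluripotency genes were at least 2-fold below H1 (median -1.17), including ZIC2 (28.6-fold), THY1 (14.5-fold), the WNT antagonist SFRP2 (11.4-fold), SOX2 (4.37-fold) and POU5F1 (3.43-fold). Metallothioneins (-2.58, 7 of 10, MT1G 22.8-fold), FGF and ERK targets (-1.34, 11 of 21, SPRY1 8.56-fold) and glycolysis and hypoxia genes (-1.21, 16 of 29, ALDOC 8.03-fold) were again lower, and interferon and HLA (-0.47) and neural ectoderm (-0.25, STMN2 12.5-fold) stood apart too. AK4, a mitochondrial adenylate kinase (11.6-fold), the long non-coding RNA MIAT (11.5-fold), TM4SF18 (at least 5.99-fold) and the POU factor POU3F1 (at least 3.40-fold) were among the lowest. Of 15474 genes, 424 were at least 2-fold higher and 551 lower, so that 43.5% were higher, against 28.2% with arrays shifted to their medians and 15.5% without scaling. The sets differed here as well, naive pluripotency lost its call under 4 alternative settings (0.055) and surface ectoderm under 1 (0.14), and another probe differed by under 2-fold for TFAP2A, AHNAK, MEIS2, MT1H, SPRY1 and POU5F1.

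Between 24 h and 48 h, both within a single set, amnion and trophoblast genes were higher at the later time and pluripotency and cell cycle genes lower. The amnion list had a median of 1.17 with 10 of 17 at least 2-fold higher, including the surface protein VTCN1 (at least 11.3-fold), GABRP (at least 9.48-fold), a GABA receptor subunit, and MEIS2 (8.14-fold). The trophectoderm and early trophoblast list had a median of 0.93 with 13 of 27 at least 2-fold higher, including EPAS1 (at least 22.4-fold), PPARG, a nuclear receptor needed in placenta (at least 11.5-fold), KRT7 (6.67-fold) and CDX2 (4.09-fold). Epithelial adhesion (0.23, DSP 4.54-fold), neural crest (0.14) and BMP targets (0.12, MSX1 8.02-fold higher but ID3 2.69-fold lower) stood apart on the higher side. HAPLN1 (12.5-fold), ACP3, an acid phosphatase (at least 15.1-fold), KANK4 (9.33-fold) and EDNRB (8.84-fold) were also higher. On the lower side, 11 of 27 primed pluripotency genes were at least 2-fold lower (median -0.33, SOX2 3.28-fold), and 29 of 29 cell cycle genes were lower, none by 2-fold (median -0.29). FGF and ERK targets (-0.25), stress response and ATF4 (-0.22, PSAT1 3.04-fold), glycolysis and hypoxia (-0.19), activin and NODAL targets (-0.17), neural ectoderm (-0.09) and the cleavage stage list (-0.06) stood apart by small amounts. SOX3, a neural progenitor factor (5.48-fold), AFP, a fetal serum protein (5.30-fold), the kinase DCLK1 (4.93-fold), CAMKV (4.72-fold), SYT11 (4.48-fold) and CBLN1 (4.34-fold) were lowest. Of 16338 genes, 181 were at least 2-fold higher and 112 lower at 48 h. The cleavage stage list lost its call under 6 alternative settings (-0.0027), neural crest under 3 (0.074), activin and NODAL targets under 2 (-0.15) and glycolysis and hypoxia under 1 (-0.11), and another probe differed by under 2-fold for EDNRB, MEIS2 and DSP.

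**Figure D2:**
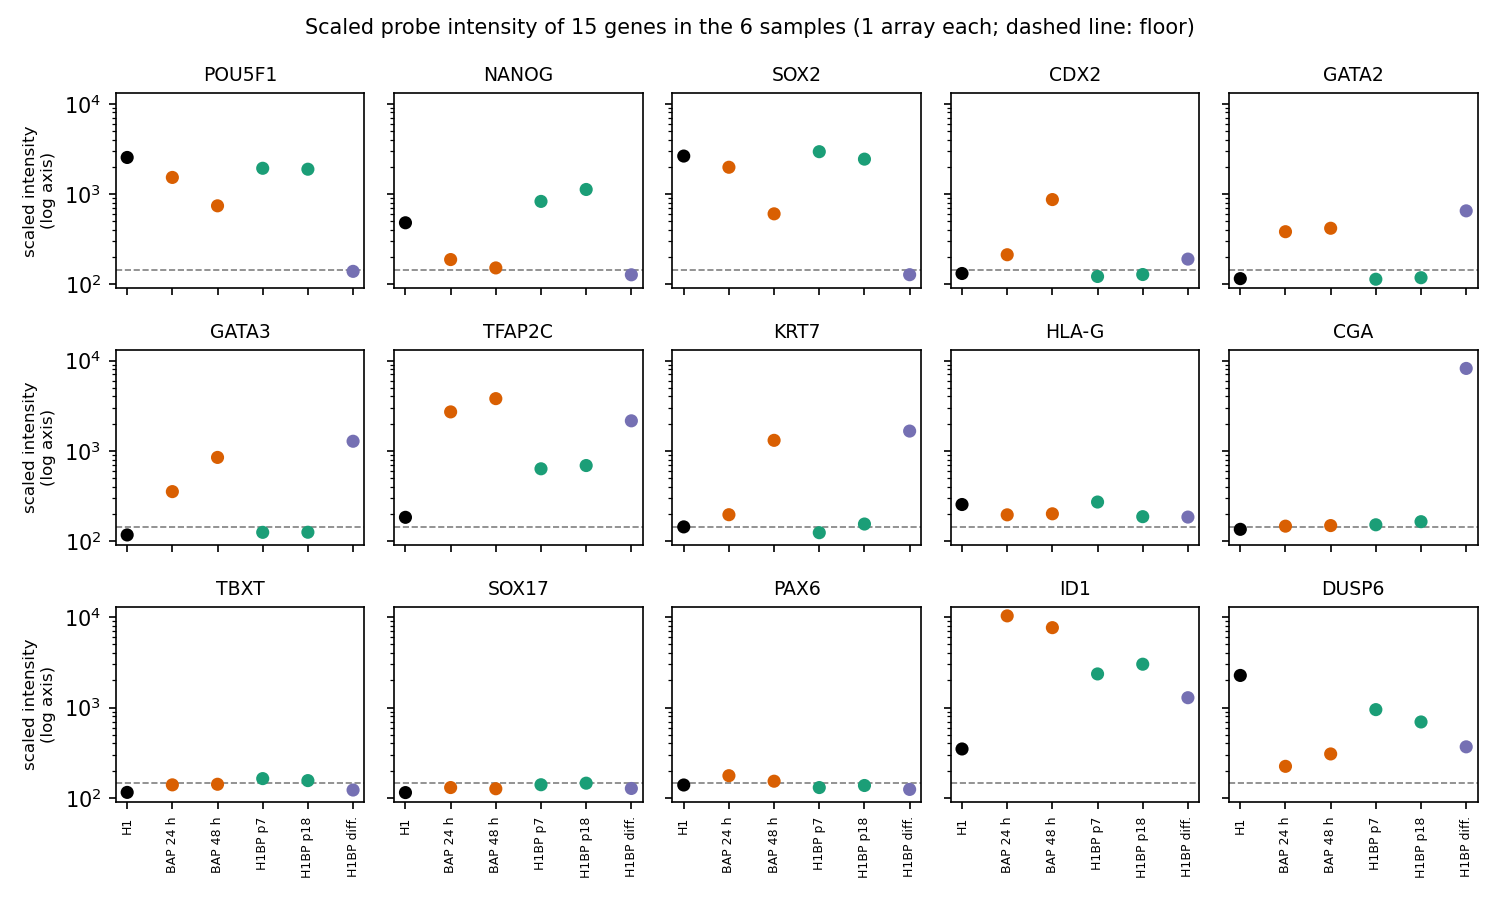
Scaled probe intensity on a log axis of 15 genes chosen before the data were examined, 1 point per array, with the floor of 145 as a dashed line. TFAP2C stood at 183 in H1, 2695 and 3781 in the BAP samples, 631 and 686 in undifferentiated H1BP and 2146 in differentiated H1BP, whereas CGA stood at 8169 in differentiated H1BP and at 164 or less elsewhere.

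H1BP cells at passage 7 carried H1-like levels of the core pluripotency factors and higher levels of activin and NODAL targets. POU5F1 stood at 1927 against 2539 in H1, SOX2 at 2943 against 2632, and NANOG at 828 against 480. Of the activin and NODAL target list, 7 of 15 were at least 2-fold higher than in H1 (median 0.79), including GDF3 (14.5-fold), the T-box factor EOMES (at least 14.0-fold), the NODAL antagonists LEFTY1 (at least 13.4-fold) and LEFTY2 (12.5-fold), and NODAL itself (at least 13.1-fold). Endoderm (0.79, FOXA2 at least 3.87-fold), heart and muscle (0.64, ACTA1 21.3-fold) and primitive streak and mesoderm (0.36, WNT3 at least 3.95-fold) also stood apart on the higher side. Genes under the floor in H1, such as FOXA2 and WNT3, were compared only where they were above it at passage 7. They could therefore only count as higher. With no filter and no floor, the endoderm and heart and muscle medians were 0.049 and 0.050, and neither stood apart. The immediate early genes FOS (13.6-fold) and FOSB (9.94-fold), the arrestin ARRB1 (13.1-fold), GAD1, which makes GABA (12.3-fold), the caveolae protein CAV1 (9.91-fold) and ABHD12B (at least 15-fold) were among the highest. GATA2, GATA3, CDX2 and KRT7 lay under the floor, as in H1, while TFAP2C was 3.45-fold and ID1 6.78-fold higher. The trophectoderm (0.25) and BMP target (0.11) lists that hold TFAP2C and ID1 did not stand apart, and ID2, also a BMP target, was 2.49-fold lower.

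Lower than in H1 at passage 7 were metallothioneins (median -1.74, 5 of 9 at least 2-fold lower, MT1E 4.77-fold), glycolysis and hypoxia genes (-0.81, 12 of 29, PFKFB4 5.35-fold), neural ectoderm (-0.57, STMN2 9.82-fold), germ cell and imprinting-related genes (-0.27, DLK1 at least 11-fold) and cholesterol synthesis (-0.18, none by 2-fold). IGFBP2, a binding protein for insulin-like growth factors (8.52-fold), DDIT4, an inhibitor of mTORC1 signalling (8.52-fold), PLA2G4C (13.5-fold), BTBD17 (8.32-fold), SYT11 (8.03-fold), the WNT antagonist SFRP1 (6.93-fold), SHISA2 (5.97-fold), the pentraxin NPTX2 (at least 5.76-fold) and TRIM4 (at least 4.05-fold) were among the lowest. Of 12517 genes, 168 were at least 2-fold higher and 239 lower. Line and medium cannot be separated here, endoderm lost its call under 3 alternative settings (0.049), heart and muscle under 2 (0.050) and the germ cell list under 1 (-0.083), and another probe differed by under 2-fold for ID1, DLK1 and TRIM4.

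At passage 18, H1BP cells differed from H1 most in collagen and other matrix genes, alongside activin and NODAL targets. Of the fibroblast and extracellular matrix list, 18 of 30 were at least 2-fold higher (median 1.34), including the collagens COL3A1 (18.5-fold) and COL6A3 (15.6-fold), the small proteoglycan LUM (at least 9.65-fold) and IGFBP7 (at least 17.0-fold). Activin and NODAL targets had 8 of 14 at least 2-fold higher (median 1.23), including LEFTY1 (at least 13.9-fold), LEFTY2 (6.98-fold) and TGFBI, a matrix protein induced by TGF-β (11.6-fold). H19, an imprinted non-coding RNA (12.6-fold), CAV1 (11.9-fold), CD44, a hyaluronan receptor (11-fold), the BMP antagonist GREM1 (10.4-fold), the galectin LGALS1 (9.23-fold) and COL8A1 (at least 7.99-fold) were also among the highest. H19 and COL3A1 stood next to the floor in H1 (145.4 and 145.7), so their folds are close to bounds. Neural crest (0.50, MSX1 5.32-fold), trophectoderm and early trophoblast (0.41, HAND1 at least 7.15-fold), BMP target (0.40, ID1 8.69-fold), amnion (0.38), primitive streak and mesoderm (0.38, WNT5A at least 5.90-fold), surface ectoderm and keratinocyte (0.31), naive pluripotency (0.30), HOX (0.28, HOXB5 3.14-fold), heart and muscle (0.28), primed pluripotency (0.19, GAL 7.47-fold), epithelial adhesion (0.18) and endoderm (0.15) stood apart by smaller medians. Among BMP targets, ID2 was 2.50-fold lower. POU5F1 stood at 1882, SOX2 at 2433 and NANOG at 1122.

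Lower than in H1 at passage 18 were glycolysis and hypoxia genes (median -0.69, 10 of 29 at least 2-fold lower, PFKFB4 5.66-fold), metallothioneins (-0.62, 4 of 9), neural ectoderm (-0.57, FABP7 4.59-fold), cholesterol synthesis (-0.41, FASN 2.31-fold) and FGF and ERK targets (-0.28, EGR1 4.35-fold). The imprinted gene NNAT (at least 44.0-fold), the mitochondrial protein CHCHD2 (14.3-fold), PLA2G4C (11.6-fold), SYT11 (11.5-fold), BTBD17 (10.1-fold), MIAT (5.91-fold) and ECHDC3 (at least 5.73-fold) were the lowest. Of 12664 genes, 280 were at least 2-fold higher and 187 lower. Of the smaller medians, endoderm lost its call under 7 alternative settings (0.057), epithelial adhesion under 5 (0.12), surface ectoderm under 4 (0.022), neural crest under 4 (0.062), heart and muscle under 3 (0.059), trophectoderm under 3 (0.13) and naive pluripotency under 2 (0.052). HOX (0.16), primed pluripotency (0.092) and primitive streak (0.018) lost theirs under 1 each. Another probe differed by under 2-fold for ID1, GREM1, LUM and NANOG.

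Between the H1BP passages the matrix genes separated the samples. Of the fibroblast and extracellular matrix list, 17 of 30 were at least 2-fold higher at passage 18 than at passage 7 and none lower by that size (median 1.10), including BGN, which encodes biglycan (16.4-fold), IGFBP7 (14.9-fold), COL3A1 (at least 18.7-fold) and COL6A3 (at least 17.8-fold). TGFBI (27.2-fold), LGALS1 (23.3-fold), IGFBP5 (14.1-fold), H19 (11.3-fold), the small RNA SNAR-A1 (10.6-fold), GREM1 (9.88-fold) and PAPPA, a placental protease (at least 11.3-fold), were the other large differences. Metallothioneins (0.82, MT2A 2.98-fold), neural crest (0.45), amnion (0.38), BMP target (0.33), trophectoderm (0.23), stress response and ATF4 (0.22), cell cycle inhibitors and p53 targets (0.18, CDKN1A 3.90-fold) and interferon and HLA (0.13) also stood apart on the higher side, and no list did on the lower. Of the stress response and ATF4 list, however, 1 of 25 genes was at least 2-fold higher and 3 were lower, namely FOS, EGR1 and JUN. Its mean log2 difference was -0.12. FOS (15-fold), FOSB (at least 11.5-fold) and EGR1 (11.6-fold), which respond within minutes to stimulation, CHCHD2 (14.7-fold), GAD1 (6.78-fold), EOMES (4.68-fold), SYT4 (4.54-fold), ARRB1 (4.03-fold) and NNAT (at least 11.9-fold) were lower at passage 18. Of 12489 genes, 237 were at least 2-fold higher and 84 lower, and 95% of genes differed by less than 0.76 in log2. BMP target lost its call under 2 alternative settings (0.10), interferon and HLA under 4 (0.096), and cell cycle inhibitors and p53 targets under 2 (0.11). With the floor halved, neural crest (0.045) and trophectoderm (0.079) lost theirs too. Another probe differed by under 2-fold for GREM1, LUM, NNAT and ARRB1.

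**Figure D3:**
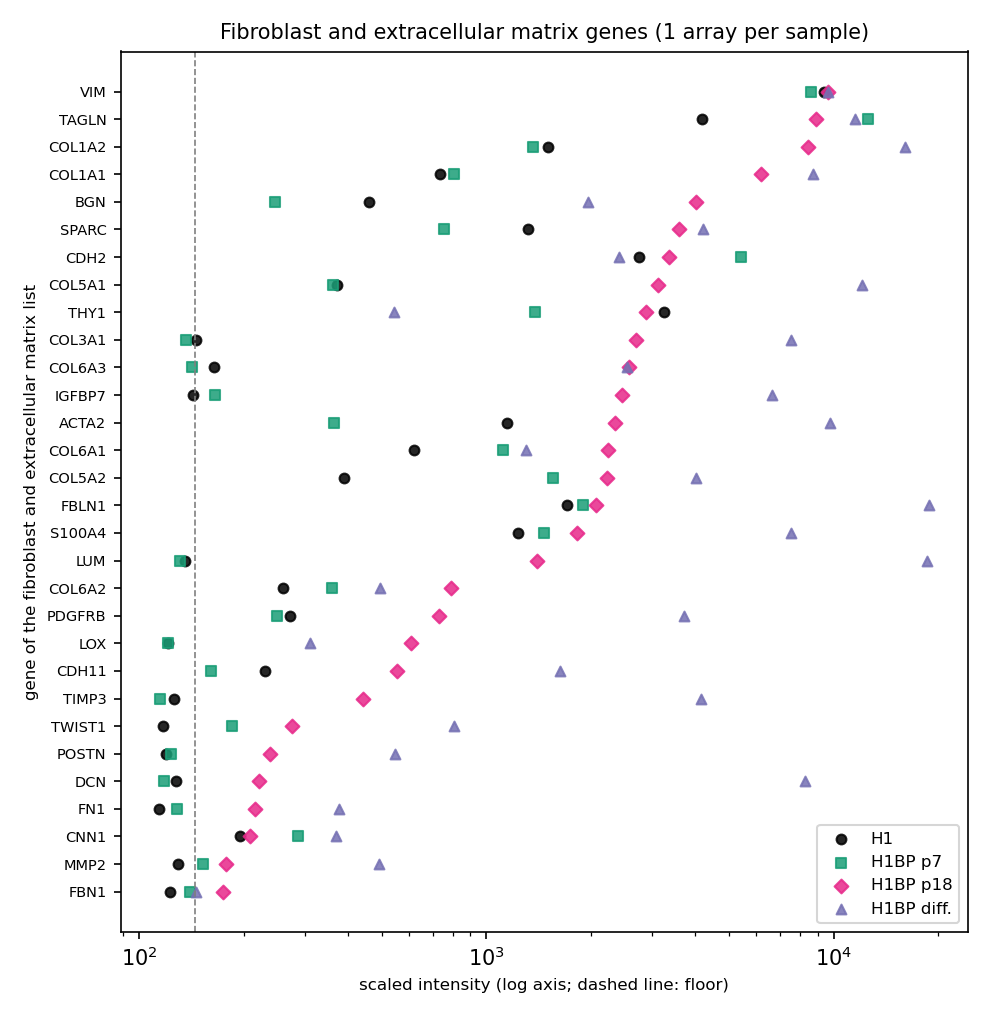
Scaled intensity on a log axis of the 30 fibroblast and extracellular matrix genes in H1, undifferentiated H1BP at passages 7 and 18 and differentiated H1BP, 1 point per array, with the floor of 145 as a dashed line. COL3A1 stood at 2698 at passage 18 and at 7535 in differentiated H1BP, and under the floor at passage 7.

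Whether differences present after 24 h of BAP were also found in the lines derived after such exposure was asked by overlap. Among genes at least 2-fold lower than in H1 after 24 h of BAP, 115 were also lower in H1BP at passage 7 and 101 at passage 18, including DUSP6, the metallothioneins MT1E, MT1G, MT1H and MT1M, and the glucose metabolism genes SLC2A1, HK2, PFKFB3 and PFKFB4. Among genes at least 2-fold higher, 42 were also higher at passage 7 and 70 at passage 18, including ID1, TFAP2C, ANXA1, CAV1 and ACTA1. All of these comparisons used the same H1 array, so simulated unchanged samples sharing 1 control array were set beside them. These gave a mean of 46.1 shared lower genes (at most 69) for passage 7 and 50.2 (at most 71) for passage 18, and 46.7 (at most 65) and 49.2 (at most 80) shared higher genes. The shared lower genes therefore exceeded the simulations, and the shared higher genes lay within their range. The simulations held no difference between the normalized sets, so the excess of shared lower genes need not come from BAP exposure. The simulated noise also holds any real difference between the H1BP samples, which would raise the simulated counts. An excess of shared higher genes therefore cannot be excluded. The correlation of the log2 differences was 0.51 and 0.53. Its simulated value of 0.50 follows from sharing 1 control at any size of noise, so it decides nothing. The covariance was 0.102 and 0.112 against a simulated 0.074 and 0.076. Genes higher in all of the 24 h BAP, passage 7 and passage 18 samples numbered 28, and genes lower in all numbered 81. At passages 7 and 18, 74 genes were higher and 122 lower than in H1 at both, against at most 69 and 70 in the simulations. The H1 array cannot be split, and its own deviations would enter every one of these overlaps.

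Against 24 h of BAP directly, both H1BP samples had lower trophoblast and BMP target genes and higher pluripotency genes. At passage 7, BMP targets had a median of -1.26 with 11 of 20 at least 2-fold lower, and trophectoderm genes -0.55 with 10 of 25, including TFAP2A (at least 39.9-fold), HAND1 (24.3-fold), DLX5 (at least 20.7-fold) and SMAD6 (10.2-fold). Primed pluripotency (0.89, 11 of 28), activin and NODAL targets (0.69, LEFTY2 15.4-fold), FGF and ERK targets (1.09, FOS 18.3-fold), metallothioneins (0.95), DNA methylation and chromatin (0.23) and interferon and HLA (0.17, IFITM1 18.3-fold) were higher. NPPB (12.3-fold), EEF1A2 (11.1-fold), the amino acid transporter SLC7A3 (9.57-fold) and CLDN10 (8.94-fold) were among the lowest genes. Heart and muscle (-0.23) and amnion (-0.39) were lower, as were epithelial adhesion (-0.31), fibroblast and extracellular matrix (-0.22), stress response and ATF4 (-0.17), surface ectoderm (-0.17) and cholesterol synthesis (-0.16), but these last 5 had medians above 0 without scaling. The primitive streak and mesoderm list stood apart on the higher side of random lists with a median of -0.01, but lost its call under 5 alternative settings, among them no scaling (0.33) and the floor halved (-0.14). Interferon and HLA lost its call under 4 (0.11), surface ectoderm under 3 (0.061), and DNA methylation and chromatin (0.16) and the fibroblast list (-0.077) under 1 each. In all, 222 of 15358 genes were at least 2-fold higher and 243 lower. The share higher was 47.7%, against 66.0% with arrays shifted to their medians and 84.7% without scaling, and these arrays came from different sets.

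At passage 18, the comparison with 24 h of BAP gave medians of -1.06 for BMP targets (10 of 20 at least 2-fold lower, ID2 7.69-fold), -0.55 for trophectoderm genes (9 of 25, TFAP2A 19.9-fold) and -0.37 for cholesterol synthesis. Metallothioneins (1.83, MT1G 9.21-fold), the fibroblast and extracellular matrix list (1.71, 19 of 30, BGN 22.9-fold), primed pluripotency (1.15, 16 of 29), activin and NODAL targets (0.92, LEFTY1 at least 13.8-fold), FGF and ERK targets (0.52, SPRY1 3.99-fold), interferon and HLA (0.24), primitive streak and mesoderm (0.11) and HOX (0.04, but -0.13 with the floor halved) were higher. Heart and muscle (-0.29, ACTC1 22.7-fold), epithelial adhesion (-0.25) and ribosomal protein genes (-0.17) were lower, but above 0 at 0.011, 0.13 and 0.21 without scaling. HOX lost its call under 3 alternative settings and ribosomal protein under 2 (-0.056). IGFBP5 (15.3-fold), IGFBP7 (12.3-fold) and H19 (at least 11.9-fold) were among the highest genes, and CHCHD2 (12.5-fold), SYT11 (11.9-fold) and EFNA1, an ephrin (10.0-fold), among the lowest. Of 15420 genes, 299 were at least 2-fold higher and 163 lower, so that 64.7% were higher, against 78.2% with arrays shifted to their medians and 89.9% without scaling. These arrays too came from different sets, and another probe of TFAP2A and ACTC1 differed by under 2-fold from BAP in both H1BP samples.

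Differentiated H1BP cells, compared with undifferentiated H1BP cells of the same passage, had higher placental hormone, trophoblast, amnion and matrix genes. Of the placental hormones and mature trophoblast list, 15 of 22 were at least 2-fold higher (median 2.25), including CGA (54.0-fold), HSD3B1, an enzyme of progesterone synthesis (at least 93.0-fold), and the chorionic gonadotropin beta genes CGB5 (at least 17.2-fold) and CGB1 (at least 16.9-fold), whose sequences are nearly identical. CGA stood at 151 at passage 7, near the floor, so its fold is close to a bound. The trophectoderm and early trophoblast list had 20 of 27 at least 2-fold higher (median 2.17), including EPAS1 (at least 86.0-fold), HAND1 (73.3-fold), S100P (at least 32.5-fold), KRT7 (at least 11.4-fold) and GATA3 (at least 8.82-fold). Amnion genes had 16 of 18 (median 2.43), including IGFBP3 (59.5-fold), VTCN1 (at least 39.9-fold) and GABRP (at least 37.3-fold), and fibroblast and extracellular matrix genes 22 of 30 (median 2.42), including LUM (at least 128-fold), DCN (at least 57.3-fold) and COL3A1 (at least 52.1-fold). Heart and muscle (1.76, ISL1 at least 13.5-fold), BMP target (1.51), HOX (1.00, HOXB5 11.5-fold), surface ectoderm and keratinocyte (0.87), epithelial adhesion (0.74, KRT8 8.57-fold), cell cycle inhibitors and p53 targets (0.54, CDKN1C 27.9-fold), neural crest (0.44), interferon and HLA (0.36, IFI6 17.3-fold), germ cell and imprinting-related genes (0.31, but -0.024 with the floor of the unscaled values), primitive streak and mesoderm (0.29) and endoderm (0.22, APOA2 8.79-fold) also stood apart on the higher side. H19 (137-fold), HAPLN1 (40.5-fold), KANK4 (36.5-fold) and AHNAK (34.4-fold) were among the highest single genes.

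The same comparison had 23 of 28 primed pluripotency genes at least 2-fold lower (median -1.94), including SOX2 (at least 20.4-fold), POU5F1 (at least 13.3-fold), ZIC2 (24.9-fold), POLR3G (16.6-fold) and GDF3 (16.1-fold). Cell cycle genes had 22 of 29 at least 2-fold lower (median -1.20), including the replication licensing factors MCM2 (4.17-fold) and MCM5 (3.85-fold) and the mitotic kinase AURKB (3.56-fold). Activin and NODAL targets had 8 of 15 (median -1.11), including LEFTY1 (at least 13.4-fold) and EOMES (9.43-fold), although TGFBI was 29.5-fold higher. FGF and ERK targets (-0.74, FOS 10.3-fold), DNA methylation and chromatin genes (-0.51), with the DNA methyltransferase DNMT3B (10.4-fold), and neural ectoderm (-0.43, SOX3 4.50-fold) stood apart too, as did the single genes ZSCAN10 (18.9-fold), VASH2 (12.7-fold), the neuropeptide GAL (11.8-fold), DCLK1 (11.3-fold) and CAMKV (at least 7.68-fold) by size. Lists that did not stand apart were metallothioneins (0.26), naive pluripotency (0.18), endothelium and blood (0.03), stress response and ATF4 (0.03), glycolysis and hypoxia (0.02), ribosomal protein (-0.07) and cholesterol synthesis (-0.24). Only 4 cleavage stage genes were measured in this pair, too few for a median. Of 12840 genes, 1112 were at least 2-fold higher and 850 lower. The neural ectoderm list lost its call under 5 alternative settings (-0.058) and the germ cell list under 2 (0.0084). Heart and muscle lost its call with the floor halved, at a median of 0.053, HOX with the floor doubled (0.55), and primitive streak (0.12) and endoderm (-0.71) among genes above the floor in both samples. Endoderm also lost its call against random lists not matched on signal. Another probe differed by under 2-fold for AHNAK, DCN, POLR3G and DNMT3B.

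Against H1, differentiated H1BP had the same lists at the higher extreme as against undifferentiated H1BP cells. Their medians were 2.90 for amnion, 2.55 for trophectoderm, 2.55 for fibroblast and extracellular matrix, 2.47 for placental hormones and 2.04 for heart and muscle. Primed pluripotency (-1.92), cell cycle (-1.28), neural ectoderm (-0.86), FGF and ERK targets (-0.75), glycolysis and hypoxia (-0.67) and cholesterol synthesis (-0.46) were lower. Activin and NODAL targets (0.24) and DNA methylation and chromatin genes (-0.34), both lower against undifferentiated H1BP cells, did not stand apart here. BMP target (1.89), HOX (1.00), surface ectoderm (0.87), epithelial adhesion (0.77), primitive streak and mesoderm (0.64), interferon and HLA (0.46), cell cycle inhibitors and p53 targets (0.43), endoderm (0.36) and neural crest (0.32) were higher. The largest single differences were in H19 (153-fold), LUM (at least 128-fold), HAND1 (at least 122-fold), HSD3B1 (at least 93.0-fold) and COL3A1 (51.7-fold) on the higher side. On the lower side they were in ZIC2 (30.8-fold), TMSB15A (25.8-fold), SNAR-A1 (23.2-fold), STMN3 (18.7-fold), the kinesin KIF1A (18.6-fold), SOX2 (at least 18.2-fold) and POU5F1 (at least 17.6-fold). The folds of H19 and COL3A1, which stood next to the floor in H1 (145.4 and 145.7), are close to bounds. Of 13028 genes, 1172 were at least 2-fold higher and 979 lower; passage number, medium and derivation all differed in this pair. HOX lost its call with the floor doubled (0.55), and primitive streak (0.27) and cell cycle inhibitors (0.33) did so among genes above the floor in both samples. Cholesterol synthesis lost its call with the mean of all probes (-0.31), and neural crest against random lists not matched on signal.

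**Figure D4:**
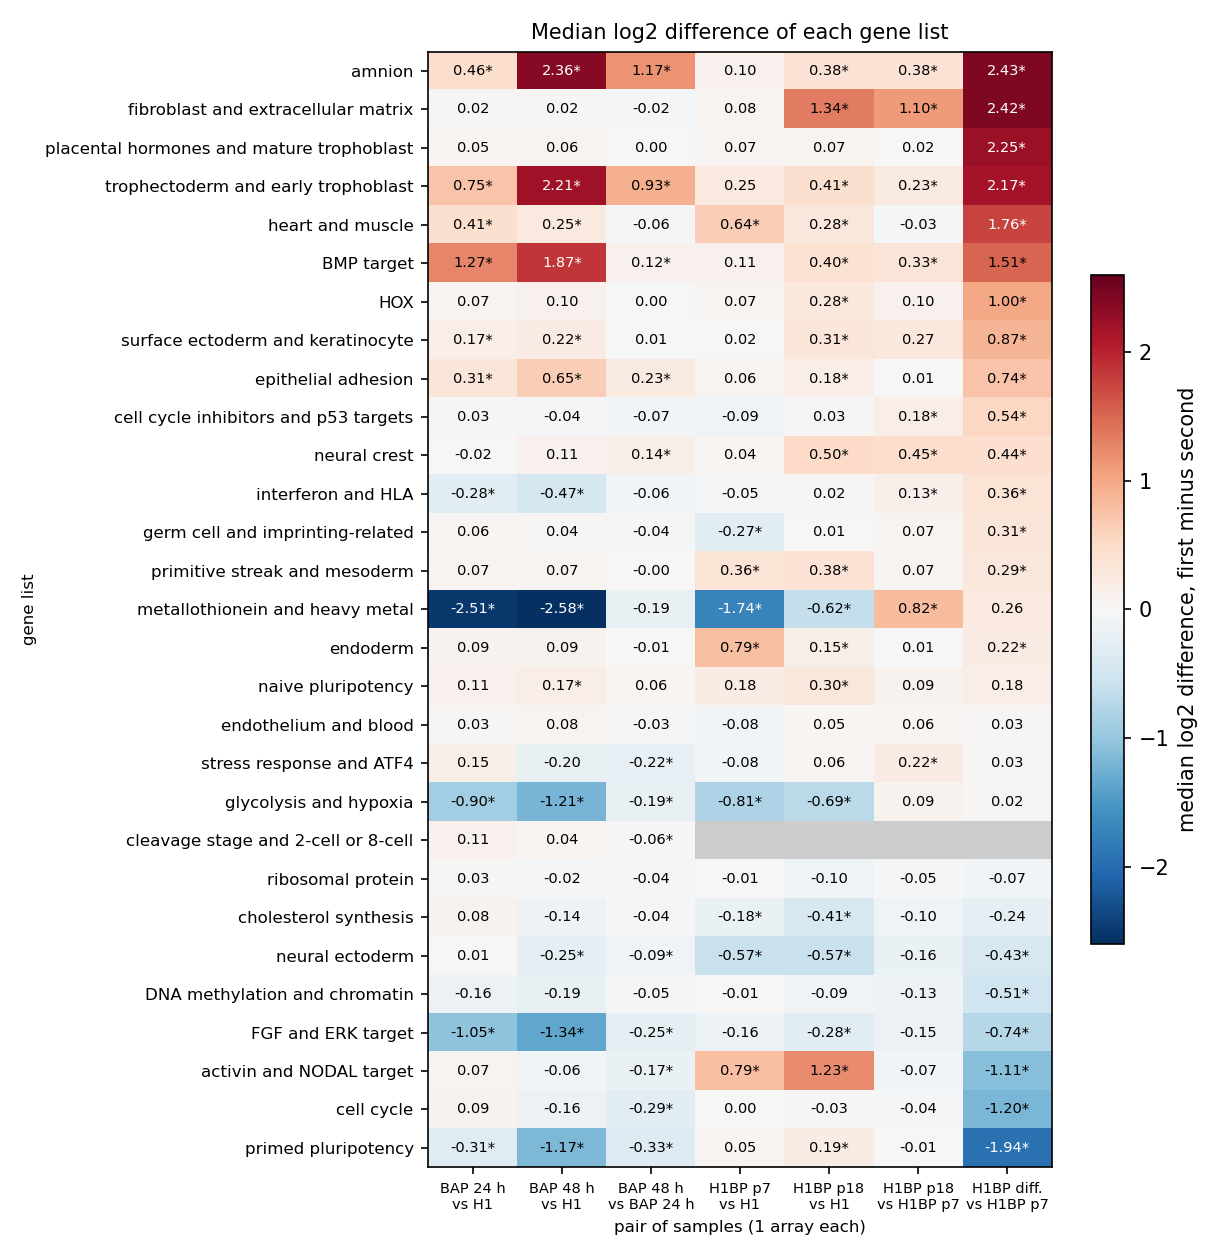
Median log2 difference of each gene list (rows) in 7 pairs of samples (columns), 1 array per sample, with an asterisk where the list stood apart from random lists and grey where fewer than 5 genes were measured. The trophectoderm list stood at 0.75 and 2.21 after 24 h and 48 h of BAP, 0.25 and 0.41 in H1BP at passages 7 and 18, and 2.17 in differentiated against undifferentiated H1BP; epithelial adhesion at 24 h and naive pluripotency at 48 h had medians below 0 without scaling, and the germ cell list in differentiated H1BP with the floor of the unscaled values.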

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

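All tests in this part were chosen after the results were seen. The 8 genes below lay at least 2-fold from H1 in opposite directions in H1BP at passage 7 and passage 18, and the difference between the samples was not tested, since each is 1 array. Given as the log2 difference at passage 7 minus that at passage 18, these were TGFBI (-4.77), LGALS1 (-4.54), IGFBP5 (-3.82), SNAR-A1 (-3.41), TM4SF1 (-2.71), ACTA2 (-2.69), DKK3 (-2.51) and EGR1 (3.53). TGFBI was at -1.24 at passage 7 and 3.53 at passage 18, ACTA2 at -1.65 and 1.04, and EGR1 at 1.41 and -2.12. No gene met this rule between the BAP samples.

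Fibroblast and extracellular matrix genes, ACTA2 among them, were higher at passage 18 than at passage 7 with a list median of 1.10. Cells with the whole profile of the differentiated H1BP sample mixed into passage 18 are argued against: 22 matrix genes stood at a median of 25.1% of the way from passage 7 to the differentiated level, but 15 placental genes at a median of 0%, and CGA measured 164 where that share would give 2164. Of 10 placental genes that such a mixture would have raised by 2-fold, 1 (PAPPA) was. Medium conditioned on mouse fibroblasts, used for both passages, is argued against as the whole cause, since the list median of passage 7 against H1 was 0.081. Fibroblast-like cells alone in passage 18, carry-over of feeder cells into that culture, the colony picked and the passage itself stay open and were not tested.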

How the results depend on the processing

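Of 242 values of the counts and overlaps under the alternatives, 202 stayed within 1.5 times the first value and 40 did not; of 10603 values of named genes, 8710 stayed within the spread between the H1BP samples, 1893 moved, and 43 of all had the other sign, none of them of a difference of 2-fold or more; of 2500 list medians, 1444 stayed within the spread of random lists, and 220 of all had the other sign, 19 of them of lists that stood apart. Each of these totals holds the halved floor and no filter, whose values were equal. Of the 145 lists that stood apart, 102 stood apart on the same side of random lists under every alternative in which enough members were measured, and 43 lost their call under at least 1. Among the 102, 96 also had a median of the same sign throughout, and 6 had a median of the other sign under at least 1 alternative. Under each single alternative between 124 and 139 kept their side. The cause of these shifts was not tested, except that no scaling leaves the difference between the sets in place, a doubled floor leaves fewer genes, and a larger size of difference takes fewer. No paired or leave-one-out analysis was possible because each group has 1 sample. Background left in the signal limits what can be seen of dim genes, whose folds it compresses.

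The scaling mattered for comparisons between the sets. Without scaling, the median of all genes moved to -0.27 for 24 h and 48 h of BAP against H1 and to 0.28 for both H1BP samples against 24 h of BAP, and with a shift to the median it was -0.10 and between 0.10 and 0.11. Without scaling, genes higher and lower numbered 135 and 918 at 24 h of BAP against H1 (236 and 315 before), 238 and 1299 at 48 h (424 and 551), 699 and 126 for passage 7 against 24 h of BAP (222 and 243), and 767 and 86 for passage 18 (299 and 163). The lower genes shared by 24 h of BAP and passage 7 numbered 174 (115). With a shift to the median, 491 genes were lower at 24 h of BAP (315), and 347 were higher at passage 7 than at 24 h of BAP (222).

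Among lists that stood apart, medians that reversed without scaling were epithelial adhesion at 24 h of BAP against H1 (-0.034) and naive pluripotency at 48 h (-0.048). For passage 7 against 24 h of BAP they were primitive streak and mesoderm (0.33), surface ectoderm (0.061), fibroblast (0.11), cholesterol synthesis (0.18), stress response (0.21) and epithelial adhesion (0.030), and for passage 18 heart and muscle (0.011), ribosomal protein (0.21) and epithelial adhesion (0.13). The germ cell list in differentiated against passage 7 also reversed in that setting (-0.024), but these arrays have equal scaling, so only the floor set anew acts there. The primitive streak median at passage 7 against 24 h of BAP was also reversed with quantile normalization (0.18), a shift to the median (0.21), a doubled floor (0.56) and genes above the floor in both samples (0.11). HOX at passage 18 against 24 h of BAP was -0.13 with the floor halved and -0.13 with no filter and no floor, and endoderm in differentiated against passage 7 was -0.71 with genes above the floor in both samples.

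With the floor doubled, genes higher and lower numbered 106 and 145 at passage 7 against H1 (168 and 239), 172 and 119 at passage 18 (280 and 187), 135 were higher at passage 18 than 7 (237), 155 were lower at passage 7 than at 24 h of BAP (243), and 45 and 76 differed from H1 at both passages (74 and 122). With normexp, 175 genes were lower at 48 h than at 24 h (112); 255 and 392 were higher and lower at passage 7 against H1; 304 were lower at passage 18 against H1; 367 and 149 were higher and lower at passage 18 against 7 (237 and 84); 337 and 375 at passage 7 against 24 h of BAP; and 268 were lower at passage 18 against 24 h of BAP. Shared genes of 24 h of BAP with passage 7 were then 65 higher and 174 lower (42 and 115), and with passage 18 112 and 155 (70 and 101). At 3-fold the same overlaps were 11 and 35 for passage 7 and 13 and 35 for passage 18. The simulations at that size gave at most 25 shared higher and 25 shared lower genes for passage 7, and 27 and 26 for passage 18.

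Past 3-fold, 50.6% of genes were higher at 24 h of BAP against H1 and 52.4% at 48 h (42.8% and 43.5% past 2-fold), and past 1.5-fold 48.8% in differentiated against passage 7 (56.7%), 48.1% in differentiated against H1 (54.5%) and 54.5% at passage 7 against 24 h of BAP (47.7%), so that in these the side with more genes depended on the size. In a count chosen after seeing the data, some BAP genes differed by 2-fold not from H1 alone but also from both undifferentiated H1BP samples. At 24 h these were 92 of 236 higher genes (39.0%) and 53 of 315 lower genes (16.8%). At 48 h they were 229 of 424 (54.0%) and 151 of 551 (27.4%).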

Other observations

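All tests in this part were chosen after the results were seen, and the genes of this paragraph were chosen after their values were seen. Several imprinted genes differed widely among the samples. H19 stood at 145 in H1, 153 and 676 after 24 h and 48 h of BAP, 163 and 1832 at H1BP passages 7 and 18, and 22296 in differentiated H1BP. In the same order, NNAT stood at 6359, 2698, 2253, 1726 and 140.3 (under the floor) in the first 5 samples, and DLK1 at 1586, 209, 781, 119.9 (under the floor), 488 and 1757. CHCHD2 stood at 256 at passage 18 and between 2606 and 3761 in the other 5 samples. TRIM4, a ubiquitin ligase, stood at 586 in H1 and at 149.9 or less in the other 5. Each of these levels is that of 1 probe. Another probe of TRIM4 differed by 0.094 in log2 between passage 7 and H1. For DLK1, another probe differed by -0.89 between passage 7 and H1 and by -0.73 between passage 18 and H1. For NNAT, another probe differed by -0.62 between passages 18 and 7, but by -1.69 between passage 18 and H1. The immediate early genes FOS, FOSB, EGR1 and JUN had their highest values at passage 7, at 3266, 1666, 2525 and 1440.3, against 241, 168, 951 and 311 in H1. CDKN1A, an inhibitor of cyclin-dependent kinases, stood at 1768 in H1, 1711 and 6677 at passages 7 and 18, and 12299 after differentiation.

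Pairs of comparisons that share no array were also set side by side. Differences between 48 h and 24 h of BAP correlated at 0.54, across genes, with those between differentiated and passage 7 H1BP, and 138 genes were at least 2-fold higher in both (15.3 for independent comparisons) and 68 lower in both (7.48). With the differences between passages 18 and 7 they correlated at 0.12. In both, 26 genes were higher and 9 lower (3.11 and 0.71 for independent comparisons), although 2 and 10 were opposite. With the differences between passage 7 and H1 the BAP differences correlated at -0.01. Even so, 8 genes were higher and 19 lower in both (1.99 and 2.14 for independent comparisons), and 15 and 11 were opposite. An excess over the values for independent comparisons can thus arise without a correlation, and alone it shows no shared direction. Passage 18 against H1 and differentiated against passage 7 correlated at 0.25, with 136 genes higher and 48 lower in both (23.4 and 12 for independent comparisons), although 33 and 21 were opposite.

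Glycolysis and hypoxia genes were below H1 in both BAP samples and both undifferentiated H1BP samples, and in differentiated H1BP as well (-0.67). Separate normalization of the sets is argued against as the whole cause, since the list median was -0.69 at passage 18, which shares a set with H1. An H1 sample that stands apart from the H1BP samples of its set is consistent with the median of 0.092 between passages 18 and 7, which did not stand apart from random lists. That pair holds no BAP sample. Against 24 h of BAP, in the other set, the list did not stand apart at passage 7 (0.060) or passage 18 (0.16). With quantile normalization it did at passage 18 (0.13). Between 48 h and 24 h of BAP the list stood apart at -0.19. Medium, cell density and derivation, any of which could have set H1 apart from the H1BP samples, were not tested, and medium differed with the line. Derivation does not apply to the BAP samples, which were H1 cells.

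Trophectoderm and BMP target genes were above H1 in both BAP samples. Over 4 scalings and both samples the lowest of the list medians was 0.56, above all of the random lists. Apart from the floor, scalings that shift a whole array move list genes and random lists alike, so they cannot decide on separate normalization. Quantile normalization across the arrays gives both sets a common distribution. The trophectoderm and BMP target medians were then 0.79 and 1.32 at 24 h, and 2.26 and 1.94 at 48 h. All lay above all of the random lists, which argues against separate normalization as the whole cause. For the trophectoderm list at 48 h, a batch shared by the BAP arrays is argued against as the whole cause, since its median between 48 h and 24 h was 0.93. The BMP target median between these times was 0.12, against 1.87 between 48 h and H1. That comparison therefore cannot tell BAP from a shared batch for most of the BMP target difference at 48 h. For the values at 24 h, with a trophectoderm median of 0.75, BAP and a batch shared by the BAP arrays cannot be told apart, because no untreated sample lies in their set. BAP stays open there, as the biological explanation that the design names.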
